A study of Mus musculus with 3 samples.

How the data were processed

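Cells from glomeruli of 3 healthy C57Bl/6 mice, 1 male, 1 female and 1 female with deletion of oestrogen receptor alpha in renal progenitor cells, were each made into 1 droplet library of 3′ gene expression tags. All 3 mice carried Pax2.rtTA, TetO.Cre and R26.Confetti, received doxycycline at 20 days and were followed to 90 days of age, per the labels. The deposited values are raw UMI counts per gene and cell, without normalisation, in barcode lists already filtered to cells by the authors. The rule of that filter is not stated. Per the submitters' processing notes, Cell Ranger 6.1.2, STAR 2.7.5a and the mm10 genome were used, on reads of a NextSeq500, with no parameters given. Of 31058 rows of the gene table, 31011 were matched by Ensembl gene ID to the GENCODE M21 annotation of GRCm38, the assembly that mm10 names, which gave the positions. The table also holds 5 fluorescent reporter sequences, of which 4 had UMIs. Library totals were 44585342, 44942380 and 47522141 UMIs for the male, female and female ERaKO libraries, the lowest barcode totals were 4284, 5013 and 4899 UMIs, and pairs of libraries shared 4 to 8 barcodes.

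Cells were kept with at least 500 genes and at most 25% mitochondrial UMIs, which left 3333, 2900 and 2613 barcodes, and 244, 223 and 379 barcodes had fewer genes than the minimum. Doublets were called in each library with the Scrublet method in scanpy 1.11.5 and removed (112, 53 and 142 cells, or 3.36%, 1.83% and 5.43%). Run on all barcodes before the filter, the method called almost no cell in 2 of the libraries, so it was run after the filter, an order set after this was seen. The 8539 kept cells were scaled to 10000 UMIs each, log-transformed and reduced to 30 principal components of 2000 variable genes, with the sex chromosome list and mitochondrial genes left out. Leiden clustering at resolution 1 (leidenalg 0.10.2, 15 neighbours) gave 29 clusters. A cluster was named for the best of 18 fixed marker lists if its mean log2 score was at least 1, led the next by 0.75 and had at least 3 markers 2-fold up. Its 10 top genes by fold also had to hold no more markers of any other class than of its own. These minima were set after the clusters were seen. This named 13 classes and left 6.40%, 7.80% and 6.39% of cells unnamed, among them cluster 5, with podocyte markers beside Cst12, Pla2g7 and Dkk3. Cluster 5 met the minima for podocytes and stayed unnamed only because of its 10 top genes. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9 were used.

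Groups were those of the labels, and the comparisons were male against female and female ERaKO against female in 5 planned classes (podocyte, parietal epithelial, endothelial, mesangial and proximal tubule cells), each with at least 30 cells in each library. With 1 library per group there is no test of a difference and no p-value, because cells of 1 mouse are not replicates. Counts were summed over the cells of a class and scaled to 1e6 UMIs per class (CPM), and log2 ratios were taken with a pseudocount of 1 CPM. Their 95% intervals are exact conditional intervals of the ratio of 2 Poisson counts without the pseudocount, and shares have exact Clopper-Pearson intervals. For a count of 0, the limit is that of 3 counts or 3 cells. All intervals and limits cover counting error only, not the spread between mice. Podocyte sums rested on 10521386, 15656242 and 7168436 UMIs and mesangial sums on 1387798, 447569 and 1329951.

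Named genes are the 10 highest and 10 lowest log2 ratios in podocyte and parietal epithelial cells and the 5 highest and 5 lowest in endothelial, mesangial and proximal tubule cells, where 1.5-fold or more. They needed at least 100 summed counts, 30 CPM in the higher library, at least 0.25 of the highest CPM in another class and at most 20% of counts in 1 cell, and the share of cells with a UMI had to differ in the same direction. Ribosomal, mitochondrial, haemoglobin, predicted and Y-linked genes, Xist, Tsix, markers of other classes and the immediate early and heat shock lists were left out, and some genes that met the rule are not reported here. For genes shifted in both contrasts, the 5 highest and 5 lowest by the smaller ratio were named. There were 22 fixed gene lists: slit diaphragm and foot process, podocyte transcription factors, basement membrane and secreted factors, oestrogen response, hormone receptors, renal progenitor, Notch, retinoid, cell cycle, injury and fibrosis, oxidative phosphorylation, unfolded protein response, interferon and antigen presentation, cholesterol synthesis, angiogenic genes, endothelial tone and shear response, mesangial matrix and contraction, immediate early, heat shock, male-biased and female-biased proximal tubule, and sex chromosome genes. Members absent under their listed symbol were matched through the gene IDs and synonyms of the reference gene table. A list's value is the median log2 ratio of members with at least 20 summed counts in the 2 libraries, with its percentile among 10000 random lists matched on mean level, as a description of these libraries and not a test. The filters, classes compared, naming rule, lists and 26 alternatives were fixed before the data were examined.

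The correlation of the contrasts over genes of at least 50 CPM was set beside 100 Poisson simulations of unchanged groups that share the female counts. Cycling cells were those with 2 or more UMIs over 12 mitotic genes. For shares that depend on depth, each cell was also thinned to 2000 UMIs, which left out no cell. Alternatives were a looser cell filter (200 genes, 50% mitochondrial) and a stricter one (1000 genes, 10%), doublets kept, resolutions of 0.5 and 2, each library clustered separately and classes assigned cell by cell from the markers. They also included TMM factors of edgeR 4.0.16 in R 4.3.3 and median-of-ratios factors, each cell scaled equally, thinned cells, a pseudocount of 5 CPM, list members with at least 5 or 100 counts, and lists without members under 0.25 of their level in another class. A further 9 were added after the data were seen, with 4 added gene lists. The log2 ratios, intervals and list percentiles were tested on simulated counts with known changes in every class and contrast. These counts were Poisson draws around the pooled class counts, the same model that the intervals assume. They held no spread between mice or cells and no free RNA, and cell filtering, doublet calls, clustering and class naming were not simulated. The values below thus cover counting error only and give no rate of false calls between mice. Changes of 2-fold and 4-fold passed 1.5-fold in the right direction for 94.7 to 100% of genes and changes of 1.5-fold for 41.6 to 56.9%, while 0 to 2.70% of unchanged genes passed. Intervals held the true value for 91.5 to 100% of genes, and 3.0 to 9.5% of random lists lay outside the central 95% of percentiles. The reporter sequences were not among the planned comparisons.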

Results

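Glomeruli, the filters of the kidney, were prepared from 1 male mouse, 1 female mouse and 1 female mouse lacking oestrogen receptor alpha in renal progenitor cells (female ERaKO), and their cells were profiled by droplet RNA sequencing of 3′ tags with molecular identifiers (UMIs). All 3 mice carried a doxycycline-induced Pax2 driver of Cre and the Confetti colour reporter, were induced at 20 days and were followed until 90 days of age. Each group is a single mouse and a single library (n = 1), so no difference between groups could be set against a spread between animals, and every interval covers counting error only. The deposited tables held 4244 barcodes with 44585342 UMIs in the male library, 3555 with 44942380 in the female library and 3986 with 47522141 in the female ERaKO library. After filtering, 3221, 2847 and 2471 cells were kept, with median depths of 7325.0, 8857.0 and 8039.0 UMIs. The share of barcodes with more than 25% mitochondrial UMIs was 21.0%, 17.8% and 34.0% in the same order, so the female ERaKO preparation lost the most barcodes to that filter.

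Podocytes, the epithelial cells that wrap the glomerular capillaries, formed the most numerous class of each library, followed by endothelial cells. Classes are named for the markers of their clusters and stand for podocyte-like, parietal epithelial-like cells and so on. Podocytes made up 35.6% of the male cells (exact 95% interval 34.0 to 37.3), 47.1% of the female cells (45.2 to 48.9) and 31.9% of the female ERaKO cells (30.05 to 33.8). Parietal epithelial cells, which line Bowman's capsule and include cells regarded as podocyte progenitors, made up 3.79% (3.16 to 4.51), 2.78% (2.20 to 3.45) and 8.42% (7.35 to 9.58). Per 100 podocytes and parietal cells together, 90.4 were podocytes in the male library (88.6 to 92.0), 94.4 in the female library (93.1 to 95.6) and 79.1 in the female ERaKO library (76.5 to 81.6), or 9.40, 17.0 and 3.79 podocytes per parietal cell. Endothelial cells came to 24.0%, 24.2% and 19.3%, mesangial cells to 6.18%, 1.76% and 5.79%, smooth muscle and renin cells to 8.57%, 5.37% and 9.59%, and proximal tubule cells to 5.25%, 4.11% and 10.5%. The male podocyte share was 21.1% when each library was clustered separately, below the female ERaKO share under that setting, and the tubule shares were 2.26%, 0.843% and 3.44% under a stricter cell filter. Within podocytes, cluster 0 held 608, 591 and 452 cells and cluster 1 held 536, 740 and 332, so the female podocytes came mostly from cluster 1 and those of the other libraries mostly from cluster 0. Unnamed clusters held 6.40%, 7.80% and 6.39% of cells, and the yield of each class also depends on how each kidney was dissociated.

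**Figure D1:**
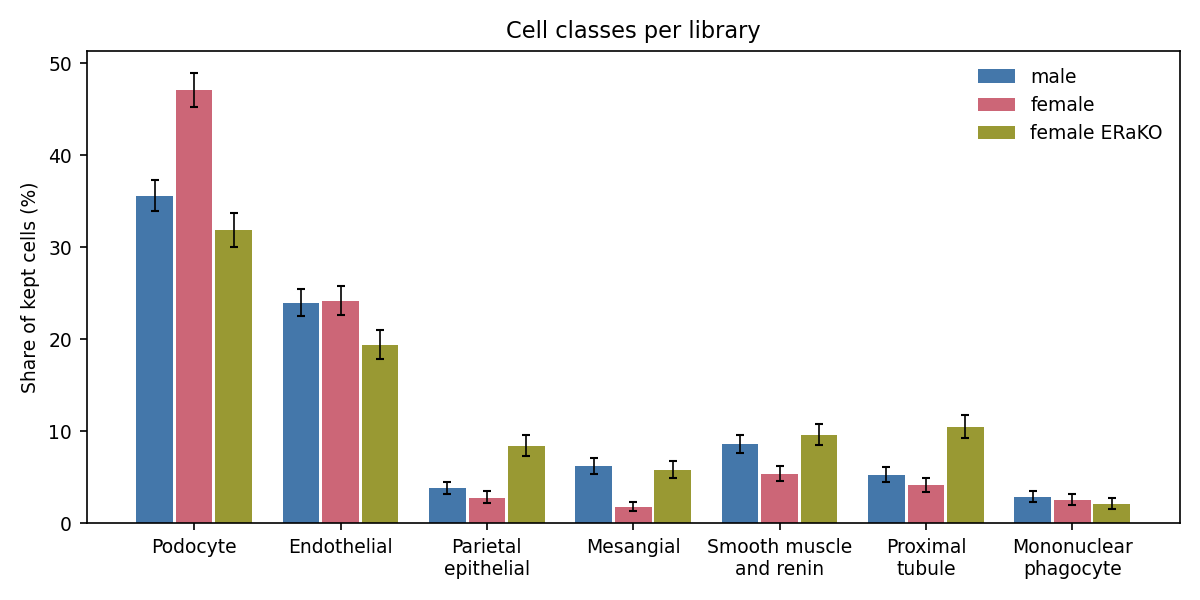
Percent of kept cells in each class (vertical axis) for the male, female and female ERaKO libraries, 1 library per group, with exact 95% binomial intervals as error bars. Podocytes stand highest in the female library at 47.1%, and parietal epithelial cells stand highest in the female ERaKO library at 8.42%.

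The targeted gene Esr1 (ENSMUSG00000019768, chromosome 10, 4611593 to 5005614 of GRCm38) was close to undetected in podocytes of every library. UMIs of Esr1 were found in 2 of 1147 male podocytes (0.174%), 1 of 1340 female podocytes (0.0746%) and 3 of 788 female ERaKO podocytes (0.381%), at median depths of 7779.0, 9202.5 and 7415.0 UMIs. Among parietal cells, 4 of 122 male cells (3.28%), 0 of 79 female cells (which allows a share of up to 3.80%) and 5 of 208 female ERaKO cells (2.40%) held a UMI, at median depths of 9324.5, 9031.0 and 11839.0. Endothelial cells showed 1.30%, 2.18% and 1.46% at 5999.5, 7551.0 and 8139.5 UMIs, so the podocyte shares lay below the endothelial ones and the parietal shares near them, and the share that free RNA alone would give was not measured. Smooth muscle and renin cells had the gene more often, with 10.9% (7.46 to 15.2), 13.7% (8.70 to 20.2) and 10.5% (6.94 to 15.2) of cells, and proximal tubule cells reached 15.4% (11.3 to 20.4) in the female ERaKO library against 5.33% and 5.98% in the male and female ones. The labels do not give the deleted part of the gene, and a 3′ tag outside it would be counted in cells with the deletion, so these values do not check the knockout.

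Sex chromosome genes followed the labels. Xist, the RNA that silences one X chromosome in female cells, stood at 0.665 CPM (counts per 1e6 UMIs of the class) in male podocytes, 1651.8 CPM in female podocytes and 1504.4 CPM in female ERaKO podocytes. Ddx3y of the Y chromosome stood at 110.4 CPM in male podocytes and had 0 counts in female podocytes (up to 0.192 CPM) and in female ERaKO podocytes (up to 0.419 CPM). Over the 10 measured members of the sex chromosome list, male over female podocytes, the median log2 ratio was −0.23 (percentile 0.02 of 10000 random lists) while the mean was 0.54, as Y genes were higher and X genes lower. Between the female libraries the median over 6 members was −0.07.

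The comparison of male with female wild-type mice asks how podocytes and their neighbours differ by sex. In podocytes, the male cells had less RNA of circadian clock output genes and more of immediate early genes, with small differences in podocyte identity genes. Dbp, a clock-controlled transcription factor, was 8.09-fold lower in the male podocytes (log2 ratio −3.02, 95% interval −3.31 to −2.87, 185 against 2337 counts). Nr1d1, a repressor within the clock, was 2.92-fold lower (log2 ratio −1.55, −1.73 to −1.42), and Per3 and Nr1d2 stood at −1.13 and −1.0. Lars2, the mitochondrial leucyl-tRNA synthetase, was 2.27-fold higher (log2 ratio 1.19, 1.13 to 1.25, 5741 against 3748 counts). Next among the 10 highest came Cyp26a1, which degrades retinoic acid (1.12, 0.94 to 1.41), Mylk3 at 0.98, and Nell2, a secreted glycoprotein (0.96, 0.85 to 1.10). Foxs1, R3hdml, Frmd6, Leo1, Cacna2d2 and Hip1r followed with log2 ratios from 0.80 down to 0.64. Other lower genes were Btg3 (−1.08), Bloc1s1 (−1.07), Hist1h4h (−0.98), Grcc10 (−0.75) and Usp50 (−1.93), the last of which has close sequence relatives and is uncertain.

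By gene list, the podocyte program itself differed little between male and female. The 19 measured slit diaphragm and foot process genes had a median log2 ratio of 0.11 (percentile 99.3), with no member 1.5-fold apart, Nphs1 (nephrin) at −0.16 and Podxl at 0.23. Podocyte transcription factors had a median of 0.13 over 7 genes (percentile 93.8) and a mean of opposite sign, −0.0027, with Tcf21 the 1 member at least 1.5-fold lower (−0.69), and Wt1 at −0.08. Basement membrane and secreted factors had a median of 0.22 over 11 genes (percentile 99.7), with Col4a4 at 0.21 and Npnt at 0.34. The 14 immediate early genes were higher as a group (median 0.48, percentile 100, 5 members 1.5-fold higher, none lower), with Atf3 at 1.32, Fosb at 0.85 and Fos at 0.63, a group that also responds to tissue dissociation. The 13 interferon and antigen presentation genes were lower (median −0.42, percentile 0.0, 4 members 1.5-fold lower, none higher), with H2-D1, a gene with close relatives, at −0.42. The oestrogen response list had a median of 0.19 over 17 genes (percentile 99.8, 3 higher, none lower), but the median was −0.0021 once members more abundant in other classes were left out. Notch pathway genes had a median of −0.25 (7 genes, percentile 2.27), injury and fibrosis genes 0.25 (9 genes, percentile 99.3, 1 higher, 2 lower), heat shock genes 0.15 (10 genes, percentile 98.4), cholesterol synthesis genes −0.13 (12 genes, percentile 2.96) and unfolded protein response genes −0.08 (10 genes, percentile 8.46). Medians were −0.07 for 25 oxidative phosphorylation genes (percentile 4.20), 0.05 for 6 hormone receptors (percentile 61.5), 0.00088 for 8 retinoid pathway genes (percentile 48.7) and 0.05 for 10 cell cycle genes (percentile 71.4, mean −0.02).

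In male parietal epithelial cells, Nfkbia, the inhibitor of NF-κB, was 2.20-fold higher (log2 ratio 1.14, 0.996 to 1.29, 1791 against 500 counts), Irf1 stood at 1.33 (1.02 to 1.68), Cebpd at 1.23 and Epcam, an epithelial adhesion molecule, at 1.09 (0.88 to 1.32). The highest ratio was that of Lsmem1 (2.35, 1.57 to 3.52, 99 against 11 counts), and Parm1, Sort1, Chd3, Foxj1 and Rilpl1 lay between 1.35 and 1.09. Lower were Serpinf1 (−1.19), Eln, the elastin gene (−1.02), the clock genes Nr1d2 (−1.06) and Tef (−1.04), and Erh, Ptgds, Coa6 and Timm21 (−1.10 to −0.96). Ptgds was higher, at 1.64, when each library was clustered on its own.

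Injury and fibrosis genes had a median of −0.39 over 14 members in male parietal cells (percentile 0.0, none higher, 6 lower), with Ccl2, a monocyte attractant, at −5.37 and Spp1 (osteopontin) at −0.51. Interferon and antigen presentation genes had a median of −0.43 over 14 members (percentile 0.0, 2 higher, 5 lower). Immediate early genes (median 0.45, percentile 100, 6 of 14 higher, Fosb at 1.47) and heat shock genes (0.37, percentile 99.9, 4 of 10 higher, Hspa1a at 1.73) were higher. With classes assigned cell by cell the immediate early median was much smaller. The renal progenitor list had a median of 0.19 over 12 members (percentile 86.3, 1 higher, 2 lower), with Pax2 at 0.61, Cd24a at 0.58 and Vcam1 at −0.83. Oestrogen response genes had a median of 0.09 over 20 members (percentile 56.1, 5 higher, none lower), with the progesterone receptor gene Pgr at 0.74. Medians were 0.01 for 6 Notch genes (percentile 33.2, Hes1 at −0.60), 0.03 for 12 basement membrane genes (percentile 35.7) and −0.23 for 18 slit diaphragm genes (percentile 0.02), which parietal cells hold at low levels and whose median was 0.08 without members more abundant in other classes.

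Male endothelial cells had more RNA of Cyp26b1, which degrades retinoic acid, 3.02-fold above the female level (log2 ratio 1.60, 1.51 to 1.70, 3533 against 1265 counts). Gadd45b (1.08), Esm1 (1.01), Egfl8 (0.92) and Sost (0.91) followed, and the lowest were Ch25h, cholesterol 25-hydroxylase (−1.56), Cd36, a fatty acid transporter (−1.55), Ccdc85b (−0.93) and H2-T23 (−0.87), which has close relatives. All 12 cholesterol synthesis genes were measured, with a median of 0.52 (percentile 100, 2 higher, none lower) and Sqle at 0.77. Retinoid pathway genes had a median of 0.24 (6 genes, percentile 99.8, 2 higher), interferon genes −0.43 (14 genes, percentile 0.0, 2 lower), immediate early genes 0.34 (14 genes, percentile 100, 2 higher) and heat shock genes 0.38 (10 genes, percentile 100, 3 higher). Angiogenic ligands and receptors had a median of 0.01 (10 genes, percentile 56.2), with Vegfc at 1.57, and the list of endothelial tone and shear response genes 0.04 (10 genes, percentile 77.5). The mesangial matrix and contraction list, markers of another cell type, had a median of −0.66 in these cells (12 genes, percentile 0.0, 2 higher, 6 lower), but it lay above 0 under 3 alternatives.

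Mesangial cells, the contractile cells of the glomerular stalk, numbered 50 in the female library, which widens their intervals. In the male ones, Rab3a (1.34, 0.53 to 2.32), Rabl6, Tspan5, Dpp8 and Gadd45b (1.12 to 1.04) were highest and Xaf1 (−1.25), Dbp (−1.19, −1.50 to −0.90), Tef (−1.04), Ppic (−1.02) and H2-T23 (−1.11) lowest. Interferon genes were lower (median −0.46, 14 genes, percentile 0.0, 6 lower), immediate early genes higher (0.53, 14 genes, percentile 100, 7 higher, Fosb at 2.14) and heat shock genes higher (0.55, 10 genes, percentile 100, 5 higher, 1 lower), while matrix and contraction genes had a median of 0.15 (11 genes, percentile 97.1).

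Proximal tubule cells, which enter a glomerular preparation as fragments, showed the known sex program of that segment. Slc7a13, an aspartate and cystine transporter, had 902 counts in male and 0 in female cells, at least 249.5-fold higher against a floor of 3 counts in the class. The bound was at least 84.6-fold for Cyp4a12a, 63.9-fold for Slco1a1 and 60.3-fold for Rnase12, and Acsm3, with 1 female count, had a ratio of 475.4 (85.0 to 18810.8). Cyp4a14 was at least 110.5-fold, Cox8b 101.2-fold and Gbp3 82.8-fold lower in the male cells, and Slc7a12 and Rdh16f2 stood at −5.98 (−6.60 to −5.63) and −5.07. The male-biased list had a median of 2.92 (11 genes, percentile 100, 8 higher, 1 lower; 2.94 with unseen genes at their bound), with Cyp7b1 at 4.43 and, against its name, Kap at −1.52. The female-biased list had a median of −4.58 (7 genes, percentile 0.0, 6 lower; −4.66 with bounds), with Prlr at −4.58 and, against its name, Adh1 at 2.61. Injury and fibrosis genes had a median of −0.01 (13 genes, percentile 6.99, 1 higher, 4 lower) and oxidative phosphorylation genes 0.12 (25 genes, percentile 52.0), the latter negative under either other scaling, as the median ratio of all genes was 0.16 under CPM and 0.02 under TMM. Different clusters held most of these cells: cluster 14 held 98 of the 169 male cells, and clusters 16 and 19 held 40 and 42 of the 117 female cells, against 1 and 0 male ones. RNA of the same tubule genes was seen at low level in podocytes, where the male-biased list had a median of 1.11 (8 genes, percentile 100) and the female-biased list −0.77 (6 genes, percentile 0.01), and how much of it was free RNA of the suspension was not measured. The male-biased median in podocytes was much smaller under several alternatives, and the female-biased one moved both ways.

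**Figure D2:**
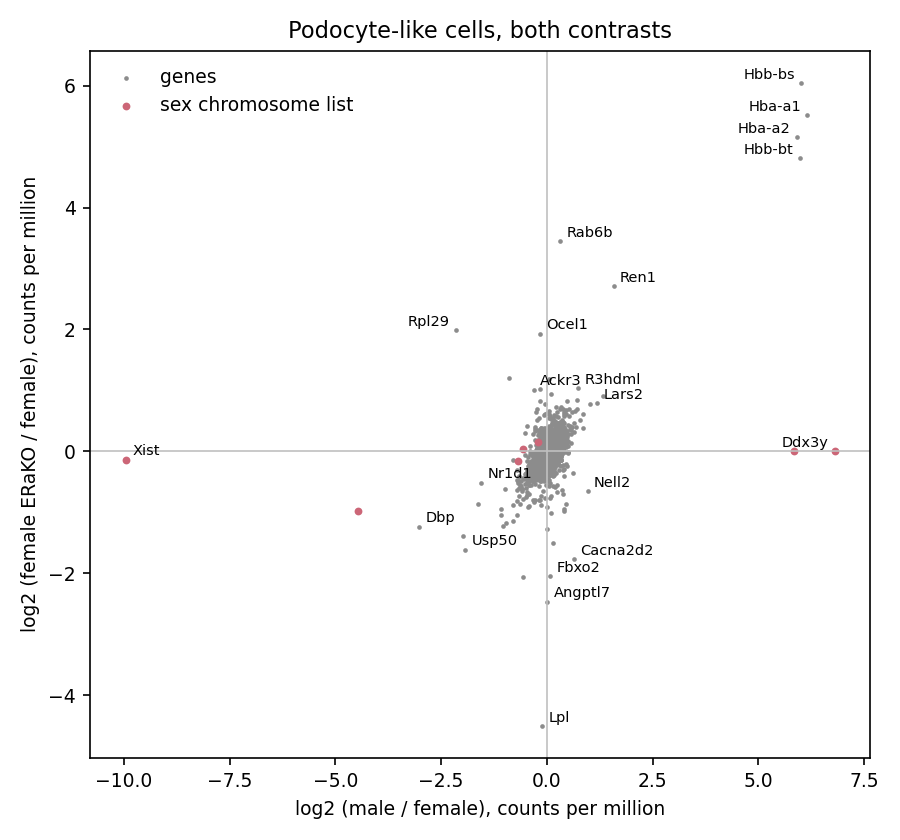
Log2 ratio of CPM in podocytes, male over female (horizontal axis) against female ERaKO over female (vertical axis), 1 point per gene with at least 50 CPM in any of the 3 libraries. Lpl lies lowest in the female ERaKO contrast at −4.50, and Dbp lies low in both at −3.02 and −1.23.

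The comparison of female ERaKO with female wild-type mice asks what loss of the receptor in renal progenitors changes in a female glomerulus. In podocytes, the gene furthest from the female level among those that met the naming rule was Lpl, which encodes the lipoprotein lipase that releases fatty acids from circulating triglycerides. Lpl (ENSMUSG00000015568, chromosome 8, 68880491 to 68907448) had 323 counts in female ERaKO podocytes against 16317 in female ones, a log2 ratio of −4.50 (−4.70 to −4.37), or 45.1 against 1042.2 CPM. Haemoglobin genes, which the rule leaves out, differed more, with Hbb-bs at 423.8 against 5.43 CPM and 57.5% of its female ERaKO counts in 1 cell. Angptl7, an angiopoietin-like secreted factor, stood at −2.46 (−2.88 to −2.24, 89 against 1143 counts), Fbxo2 at −2.05 (−2.43 to −1.83), Cacna2d2, a calcium channel subunit, at −1.77, Myl7 at −1.50, Svep1 at −1.42, Per3 at −1.37 and Gadd45gip1 at −1.27. Calm2 (−2.06) and Usp50 (−1.61) were lower too but have close relatives and are uncertain. Ocel1 (chromosome 8, 71371298 to 71379361) was 3.82-fold higher (1.93, 1.77 to 2.23, 449 against 245 counts), R3hdml 2.05-fold (1.04, 0.89 to 1.22) and Ackr3, a scavenger receptor of the chemokine Cxcl12, 2.02-fold (1.01, 0.90 to 1.15). Nrep, Fam32a, Gfod1, Fads1, Tuba1a, Pkm and Zbtb7c made up the rest of the 10 highest, with log2 ratios from 0.82 to 0.69.

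Podocyte identity genes stayed close to the female level. The slit diaphragm list had a median of −0.04 (19 genes, percentile 18.6, no member 1.5-fold apart), with Nphs1 at −0.44 and Podxl at 0.09. Podocyte transcription factors had a median of −0.13 (7 genes, percentile 4.89), with Wt1 at −0.26 and Tcf21 at −0.49, and basement membrane and secreted factors one of 0.26 (11 genes, percentile 99.99), with Col4a4 at 0.28 and Npnt at 0.26. The basement membrane median was much smaller once members more abundant in other classes were left out. Interferon and antigen presentation genes were lower (median −0.70, 13 genes, percentile 0.0, none higher, 9 lower), with H2-D1, which has close relatives, at −0.70. Immediate early genes were higher (median 0.57, 14 genes, percentile 100, 7 higher, none lower), with Nr4a1 at 1.15, Junb at 0.93 and Atf3 at 0.92. Notch pathway genes had a median of −0.51 (7 genes, percentile 0.16, 2 lower), and injury and fibrosis genes one of 0.28 (8 genes, percentile 99.3, 2 higher, 1 lower). The oestrogen response list, which holds targets of the deleted receptor in other tissues, had a median of 0.09 (16 genes, percentile 95.1, 2 higher, none lower), with Xbp1 at −0.33, Cxcl12 at −0.24 and Nrip1 at −0.10, and a median of −0.10 once members more abundant in other classes were left out. Cholesterol synthesis genes had a median of 0.23 (12 genes, percentile 99.8), which was negative at −0.09 under the same restriction. Heat shock genes stood at −0.11 (10 genes, percentile 3.88, 2 lower), unfolded protein response genes at −0.15 (10 genes, percentile 1.15), hormone receptors at −0.22 (6 genes, percentile 4.52) and retinoid genes at −0.12 (7 genes, percentile 20.6), with Aldh1a2, which makes retinoic acid, at −1.02 and its receptor gene Rarb at 0.63. Oxidative phosphorylation genes had a median of 0.02 (25 genes, percentile 59.6, mean −0.01) and cell cycle genes −0.11 (10 genes, percentile 19.5). The male-biased and female-biased tubule lists had medians of 0.05 (4 genes) and 0.64 (6 genes, percentile 99.9, 3 higher) in these podocytes.

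In female ERaKO parietal cells, Akr1e1, an aldo-keto reductase, was 14.9-fold above the female level (log2 ratio 3.90, 2.94 to 5.81, 323 against 5 counts). Fam71a (2.09, 1.46 to 2.96), Ocel1 and Lsmem1 (both 1.75) and Nfkbia (1.14, 1.01 to 1.28, 3928 against 500 counts) were higher as well, with Tmem53, Pnmal2, Slc20a2, Tchh and Sh3tc2 between 1.36 and 1.08. Gadd45gip1 stood at −1.51, Ammecr1 at −1.43, Alas1, the first enzyme of haem synthesis, at −1.27, Tef at −1.14, Per3 at −1.10 and Spcs3 at −1.09. Per3 was higher, at 0.87, with every cell thinned to 2000 UMIs. AY036118 (−2.24) and Usp50 (−1.52) were also among the 10 lowest, and are uncertain because of near-identical copies.

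Injury and fibrosis genes were lower in female ERaKO parietal cells (median −0.69, 14 genes, percentile 0.0, 1 higher, 8 lower), with Ccl2 at −3.64 and Spp1 at −0.73. The renal progenitor list had a median of 0.08 (12 genes, percentile 65.8, 1 higher, 2 lower) and a mean of −0.07, with Sox4 at 0.73, Pax2 at 0.32 and Sox9 at −0.98. Oestrogen response genes had a median of 0.19 (20 genes, percentile 97.6, no member 1.5-fold apart), with Pgr at 0.53. Basement membrane genes had a median of 0.27 (12 genes, percentile 99.8, 2 higher), which was −0.04 when classes were assigned cell by cell, and immediate early genes one of 0.15 (14 genes, percentile 96.8, 3 higher). The median was near 0 and opposite in sign to the mean for interferon genes (−0.07 and 0.0072, 14 genes), heat shock genes (−0.05 and 0.03, 10 genes) and Notch genes (−0.05 and 0.04, 7 genes, Hes1 at −0.87), and it was −0.04 for 19 slit diaphragm genes (percentile 14.3).

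Female ERaKO endothelial cells shared the lower Lpl, at −4.04 (−4.32 to −3.85, 156 against 3786 counts). Cyp26b1 was 4.37-fold higher (2.13, 2.04 to 2.23), followed by Ocel1 (1.85), Rarb, a retinoic acid receptor (1.57, 1.27 to 2.02), Borcs8 (1.13), and Tpm3-rs7 (2.0), a retained copy that is uncertain. B3gnt3 (−2.60), Lysmd2 (−1.87), Cmtm8 (−1.70) and Zbtb16, a glucocorticoid-responsive factor (−1.57), were lowest after Lpl. Retinoid pathway genes had a median of 0.53 (6 genes, percentile 99.99, 2 higher), cholesterol synthesis genes 0.51 (12 genes, percentile 100, 5 higher, none lower, Sqle at 0.85) and interferon genes −0.35 (14 genes, percentile 0.0, 4 lower). Immediate early genes (−0.16, 14 genes, percentile 0.61) and heat shock genes (−0.16, 10 genes, percentile 1.37) had medians slightly below 0 here, and the immediate early one shrank with cells thinned. Angiogenic genes had a median of −0.03 and a mean of 0.01 (10 genes, percentile 25.4, Vegfc at 1.09), and tone and shear response genes a median of −0.0062 (10 genes, percentile 37.4).

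In female ERaKO mesangial cells, Rab3a (1.44), Pdlim5 (1.41), Slc39a1 (1.17) and Cd53 (1.06) were highest, and B2m (−1.03, −1.18 to −0.88), Bst2 (−0.99), Tapbp (−1.18), Xaf1 (−1.04) and AY036118 (−1.54) lowest. Interferon genes had a median of −0.38 (14 genes, percentile 0.0, 5 lower), matrix and contraction genes 0.46 (11 genes, percentile 100, 2 higher, Myl9 at 0.81), immediate early genes 0.76 (14 genes, percentile 100, 8 higher) and heat shock genes −0.05 (10 genes, percentile 34.5). The immediate early median was much smaller with libraries clustered separately and with cells thinned. In proximal tubule cells, Akr1e1 (2.67, 2.20 to 3.43), Dcdc2a (2.02), Stra6 (1.85), Methig1 (1.84) and Nfkbia (1.78) were highest and Cox8b (−4.31, −5.37 to −3.94), Ccl28 (−2.80) and the family members Cyp2a5 (−2.92), Ugt2b38 (−2.52) and Cyp2d12 (−2.11) lowest. Medians there were 0.71 for injury and fibrosis genes (14 genes, percentile 100, 8 higher, 1 lower), −0.59 for male-biased genes (7 genes, percentile 0.03, 4 lower), −0.10 for female-biased genes (7 genes, percentile 11.3) and 0.18 for oxidative phosphorylation genes (25 genes, percentile 72.7). A list of 10 parietal genes, added later, was also higher in these cells (median 0.95, percentile 100, 8 higher), and cluster 14 held 37 of the 259 female ERaKO cells against 3 of the 117 female ones. The median of the parietal gene list turned to −3.18 with libraries clustered separately and to −0.25 with classes set cell by cell. Clustering each library on its own turned the injury list to −2.69, Nfkbia to −1.58, Stra6 to −4.01 and Dcdc2a to −0.48, and the cause was not tested.

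**Figure D3:**
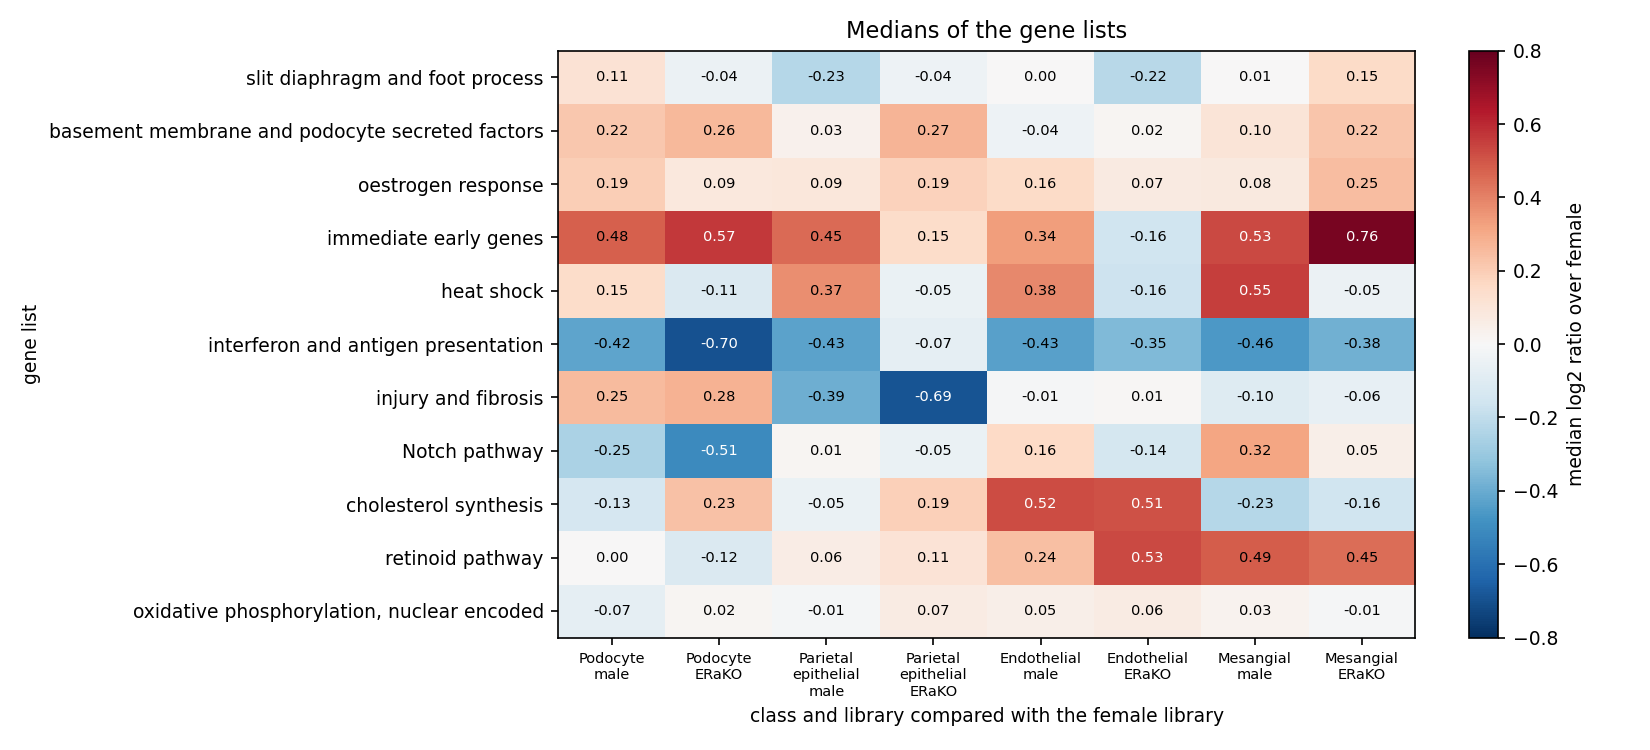
Median log2 ratio (colour and printed value) of 11 gene lists (vertical axis) in podocyte, parietal epithelial, endothelial and mesangial cells, male over female and female ERaKO over female (horizontal axis). Interferon and antigen presentation genes lie at −0.42 and −0.70 in podocytes, and cholesterol synthesis genes at 0.52 and 0.51 in endothelial cells.

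Some genes differed from the female library in the same direction in the male and the female ERaKO mouse, which bears on whether the knockout moves female cells toward the male pattern. In podocytes, R3hdml (0.74 and 1.04) and Leo1 (0.67 and 0.67), a subunit of the Paf1 transcription complex, were higher in both, and Dbp (−3.02 and −1.23), Per3 (−1.13 and −1.37), Hist1h4h (−0.98 and −1.18), Btg3 (−1.08 and −0.95) and the uncertain Usp50 (−1.93 and −1.61) were lower in both. In parietal cells, Lsmem1 (2.35 and 1.75), Nfkbia (1.14 and 1.14), Slc20a2 (1.06 and 1.26), Foxj1, a factor of ciliated cells (1.10 and 1.01), and Rilpl1 (1.09 and 0.97) were higher in both. Tef (−1.04 and −1.14), Nr1d2 (−1.06 and −0.97) and Timm21 (−0.96 and −0.94) were lower in both.

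The ratios of both contrasts share the female library, so they correlate over genes even without any difference between mice, and genes are not independent replicates. In podocytes, Pearson's r over 3580 genes was 0.535, against 0.357 (0.321 to 0.396) in 100 simulations of unchanged groups, but 4 haemoglobin genes carried much of it and r was 0.333 without them and 0.463 without them and the sex chromosome list. A single cell held 98.2% of the male podocyte counts of Hbb-bs, and another 57.5% of the female ERaKO ones. The covariance without haemoglobin genes, 0.0273, remained above the simulated 0.00141. In the other classes r was 0.557 for parietal, 0.314 for endothelial, 0.670 for mesangial and 0.302 for proximal tubule cells, each below its simulated 0.700, 0.442, 0.760 and 0.597. The covariances, 0.0870, 0.0294, 0.113 and 0.0938, were above their simulated 0.0219, 0.00317, 0.0562 and 0.0105. With separate random parts of the female cells in each ratio, and haemoglobin and sex chromosome genes included, r was 0.518 in podocytes, 0.249 in parietal, 0.302 in endothelial, 0.146 in mesangial and 0.220 in proximal tubule cells. These values describe 3 mice and a shared female animal, and cannot separate the sex or the genotype from the animal.

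Cycling cells, called by 2 or more UMIs over 12 mitotic genes, were rare among podocytes, with 0.174% of male, 0.522% of female and 0 of 788 female ERaKO cells (up to 0.381%). Parietal cells had 6.56%, 3.80% and 5.29%, and T or NK cells 18.8%, 21.3% and 40.0%. The top genes of the T or NK cluster include Mki67, Top2a and Cenpf, which belong to the 12, beside Igkc, Igha and Jchain. With every cell thinned to 2000 UMIs no podocyte and no parietal cell reached the call in any library, while 16.7%, 19.1% and 34.3% of the T or NK cells did. Cells rich in mitotic RNA could thus be called at that depth, and whether dividing parietal cells were missed there was not tested.

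**Figure D4:**
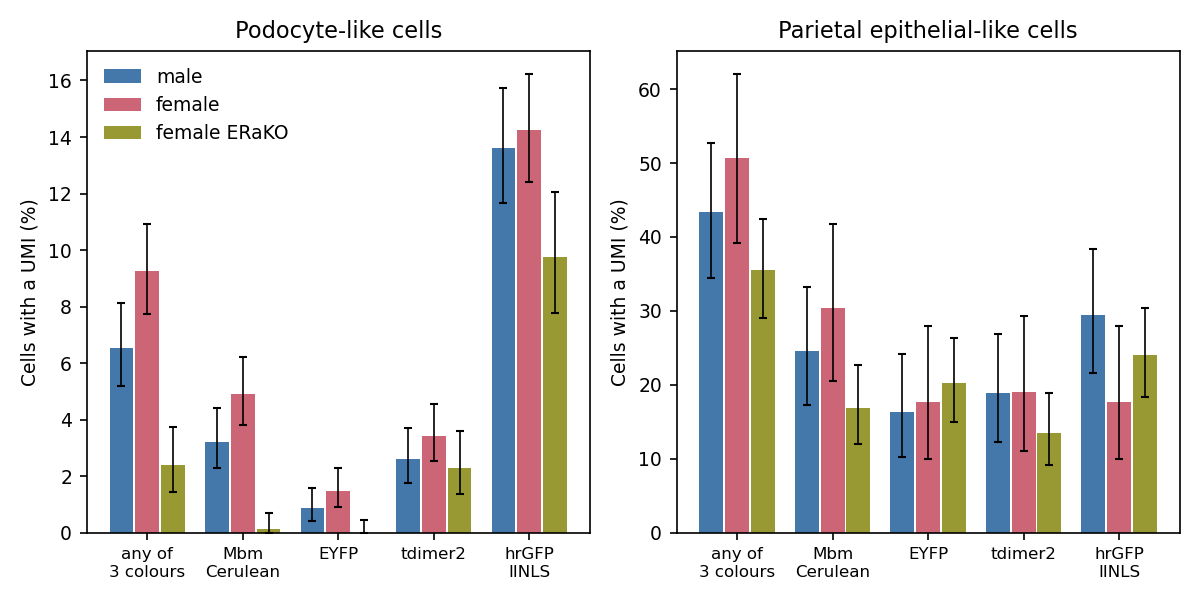
Percent of podocytes (left) and parietal epithelial cells (right) with a UMI of any of 3 colour reporters or of each reporter (vertical axis) in the male, female and female ERaKO libraries, 1 library per group, with exact 95% binomial intervals as error bars. For any of the 3 colours, female ERaKO podocytes stand at 2.41%, below the 9.25% of female podocytes.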

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

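Of the tests below, those of reporter CPM, of free reporter RNA and of weaker recombination, all but the test in proximal tubule cells and phagocytes for chromosome 8, and both for the clock genes were chosen only after the result was seen.

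Colour reporters were counted although no comparison used them, and their signal exceeded what a count of 0 allows in 3 classes. UMIs of EYFP, tdimer2 or MbmCerulean, colours that were picked after the values of each reporter were seen, were present in 6.54% of male podocytes (5.18 to 8.13), 9.25% of female podocytes (7.76 to 10.9) and 2.41% of female ERaKO podocytes (1.46 to 3.74). Parietal epithelial cells carried them in 43.4%, 50.6% and 35.6% of cells and endothelial cells, outside the Pax2 lineage, in 4.15%, 2.33% and 0.837%, at the median depths given above. MbmCerulean was found in 37 male, 66 female and 1 female ERaKO podocytes and EYFP in 10, 20 and 0, whereas tdimer2 was found in 30, 46 and 18 and the nuclear reporter in 13.6%, 14.2% and 9.77% of podocytes.

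Fewer podocytes with a colour in the female ERaKO library could mean that fewer podocytes arose from labelled progenitors after induction, a reading that stays open as untested with 1 mouse per group. Against depth alone, the 3 colours together had 2.65 CPM in female ERaKO podocytes, whose upper limit of 4.14 lay below the female lower limit of 8.05. These colours were picked after each reporter's values were seen, so this does not settle the question. Limits in female ERaKO and female podocytes overlapped for the nuclear reporter (10.1 to 15.4 and 13.7 to 17.7 CPM) and for tdimer2 alone (1.49 to 3.97 and 2.21 to 3.99 CPM). After thinning the shares with a colour were 0.635% (up to 1.47) and 1.87% and their intervals overlapped. Parietal cells caught with podocytes were argued against in the female library, where labelled podocytes held 1.12 times the parietal gene level of unlabelled ones, at most 1.30 and far from the 3 set for such doublets, while the 19 labelled female ERaKO podocytes held 1.51 times (1.15 to 1.95). Labelled podocytes were deeper than unlabelled ones, at medians of 12631.0 against 9102.5 UMIs in the female and 13716.0 against 7395.0 in the female ERaKO library. Free RNA as the whole source was argued against in the female library, where endothelial cells had 3.17 reporter CPM, at most 4.79 and below the podocyte lower limit of 8.05. By single colour, the female limits were apart for MbmCerulean (4.17 to 6.50 CPM in podocytes and 0.157 to 1.47 in endothelial cells). They overlapped for tdimer2 (2.21 to 3.99 and 1.32 to 3.74) and for EYFP (0.780 to 1.97 and 0.0349 to 1.04). For the 3 colours together, the limits overlapped in the male library (up to 7.43 in endothelial cells and from 6.54 in podocytes) and in the female ERaKO library (up to 2.12 and from 1.60). Free RNA therefore stays open in those libraries and as part of the female signal. Weaker recombination in the whole female ERaKO mouse remains open, as the parietal shares predict 6.50% of podocytes and at least 3.63%, and the observed share reached up to 3.74%. By CPM the colours were also lower in parietal cells, at 70.7 (62.8 to 79.3) in the female ERaKO against 183.3 (159.5 to 209.7) in the female library. The fall was therefore not particular to podocytes.

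Several genes shifted alike in most classes of the female ERaKO library lie in 1 stretch of chromosome 8, a stretch picked because it held the most. There were 44 genes shifted alike in all, or all but 1, of the 4 or 5 classes where they were measured. Of these, 7 lay between 70000001 and 90000000 of that chromosome, among them Ocel1, Bst2, Fam32a, Scoc, Gadd45gip1 and Asna1. Over 10000 random placements the 95th percentile was 4 and the highest was 7. The male contrast had 5 of 28 genes in 1 window of chromosome 17, against 4 and 6, so it also passed its 95th percentile. Of the genes named for female ERaKO podocytes, Ocel1, with the highest ratio, lies inside the stretch, and Lpl, with the lowest, just outside it at 68880491 to 68907448. Loss of the receptor acting only within cells of the Pax2 lineage was argued against by phagocytes, outside the lineage and not used to choose the genes. In them 6 of the 7 moved as in podocytes, with a median of 0.57 in that direction (0.25 to 1.13 over resampled cells). An effect of that loss on cells outside the lineage was not tested. Ocel1 stood at 63.1 CPM in phagocytes against 62.6 in podocytes, so podocyte RNA alone in these droplets would have to supply all of it. Endothelial cells held 114.6 CPM, and the RNA of other classes in phagocyte droplets was not measured. A strain or flanking segment that differs between the mice may account for the stretch and would bear on Ocel1 and Lpl too, but Esr1 lies on chromosome 10, and in proximal tubule cells and phagocytes 8 of 14 values (57.1%, 28.9 to 82.3) shifted 1.5-fold the same way, which decides neither way. Bst2 was lower in male podocytes too, and the segment cannot be told apart from other differences tied to 1 mouse.

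Clock output genes were lower in both other libraries than in the female one in most classes, with list medians of −1.13 in male and −0.79 in female ERaKO podocytes, −1.04 and −1.10 in parietal, −0.69 and −0.70 in endothelial, −0.50 and −0.76 in proximal tubule and −0.91 and −1.35 in smooth muscle and renin cells. In mesangial cells they stood at −0.82 and −0.15 (percentile 8.10 in the female ERaKO library, no member 1.5-fold lower), and in phagocytes at −0.33 and −0.62 over 3 and 4 genes, where random lists were often as low (percentiles 41.4 and 35.4). Loss of the receptor acting within the Pax2 lineage was argued against as the cause of the falls in female ERaKO endothelial and smooth muscle and renin cells, which lie outside it, while the mesangial median went with it and the phagocyte median, the −0.62 that was the highest of the 3 tested, decides little. Another hour of tissue collection could have shifted every class, and clock genes of opposite phase were higher in podocytes (1.09 and 0.75), parietal (1.12 and 0.86), proximal tubule (0.92 and 0.83) and endothelial cells (0.20 and 0.42) but stood at −0.08 and −0.10 in smooth muscle and renin cells. Of the 6 combinations tested in podocytes, endothelial and smooth muscle and renin cells 4 lay above 0, so the hour, which the labels do not give, stays open, as do sex and genotype, each tied to 1 mouse and untested.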

How the results depend on the processing

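Added after the data were seen were the settings for the share of podocytes with a colour, the 4 glomerular classes as denominator, cluster 5 counted as podocytes, the clock, opposite-phase, glucocorticoid and parietal gene lists, the genes and lists of smooth muscle and renin cells and of phagocytes, the correlations without haemoglobin or sex chromosome genes, and Rab6b. No paired analysis was possible because each group is 1 library and nothing in the labels pairs the mice. Alternatives gave no value with fewer than 30 cells in either library or fewer than 4 counts, a minimum set after tubule values had reversed under the stricter filter. Over all alternatives, 3974 of 4482 gene values stayed within their interval in the same direction, 487 moved and 21 reversed, in 15 results. For list medians 1774 of 1980 stayed, 185 moved and 21 reversed, in 13 results, and for shares 182 of 255 stayed, 73 moved and none reversed. The podocyte share was highest in the female library under every alternative, with 42.8% to 52.6% of all cells, and the parietal share was highest in the female ERaKO library. The order of the male and female ERaKO podocyte shares changed when libraries were clustered separately. Depth limits Esr1 and cycling calls in podocytes and parietal cells, most of which fell to 0 after thinning, and the 50 female mesangial cells limit that class. Below, male and ERaKO name the library in shares and, in log2 values, the contrast with female, lists have short names, and the cause was not tested for any moved or reversed value.

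The looser cell filter put podocyte shares at 32.5% (male), 42.8% (female) and 25.9% (ERaKO) and endothelial shares at 22.0% (male), 22.0% (female) and 16.6% (ERaKO). It put tubule shares at 5.40% (female) and mesangial shares at 4.74% (ERaKO). Slit diaphragm was −0.72 in male parietal cells, slit diaphragm was −0.37 in ERaKO parietal cells, and immediate early was 0.31 and matrix was 0.17 (reversed from −0.66) in male endothelial cells. Immediate early was −0.20 and matrix was 0.54 in ERaKO endothelial cells, and male-biased was 3.53 and injury was 0.49 in male tubule cells. Spp1 was −0.19 (reversed from 0.25), male-biased was −0.37 and oxidative phosphorylation was 0.26 in ERaKO tubule cells. The stricter cell filter put podocyte shares at 38.8% (male), 49.98% (female) and 35.3% (ERaKO) and tubule shares at 2.26% (male), 0.843% (female) and 3.44% (ERaKO). It put smooth muscle and renin shares at 8.16% (ERaKO). Immediate early was 0.60 in male parietal cells, slit diaphragm was −0.23 in ERaKO parietal cells, and matrix was 0.50 in ERaKO mesangial cells.

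Clustering each library separately put podocyte shares at 21.1% (male) and parietal shares at 5.12% (male). It put endothelial shares at 20.9% (male) and podocytes per 100 podocytes and parietal cells at 80.5 (male). Next came tubule shares at 7.41% (ERaKO). Hspa8 was 0.015 (reversed from −0.039), immediate early was 0.95, oxidative phosphorylation was −0.092 and male-biased was 0.28 in male podocyte cells. Female-biased was −1.23 in male podocyte cells, and Ptgds was 1.64 (reversed from −1.03) in male parietal cells. Progenitor was 0.26, oestrogen was 0.34 and heat shock was 0.11 in ERaKO parietal cells, and matrix was −0.26 (reversed from 0.20) in ERaKO endothelial cells. Immediate early was 0.19 in male mesangial cells, and immediate early was 0.32 in ERaKO mesangial cells. Injury was −0.56, oxidative phosphorylation was 0.17 and parietal genes was −0.96 (reversed from 0.59) in male tubule cells. Dcdc2a was −0.48 (reversed from 2.02), Stra6 was −4.01 (reversed from 1.85), Nfkbia was −1.58 (reversed from 1.78) and Kap was 0.41 (reversed from −0.38) in ERaKO tubule cells. Abcc3 was 0.47 (reversed from −0.29), Ccl2 was −6.51 (reversed from 1.27), Spp1 was −2.69 (reversed from 0.25) and male-biased was −0.21 in ERaKO tubule cells. Female-biased was 0.52, injury was −2.69 (reversed from 0.71), oxidative phosphorylation was 0.38 and parietal genes was −3.18 (reversed from 0.95) in ERaKO tubule cells. Opposite-phase clock was −0.12 (reversed from 0.83) in ERaKO tubule cells.

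Counting cluster 5 as podocytes put podocyte shares at 40.2% (male), 52.6% (female) and 34.9% (ERaKO). Taking 4 glomerular classes as the denominator put podocyte shares at 51.2% (male), 62.1% (female) and 48.7% (ERaKO) and parietal shares at 5.45% (male), 3.66% (female) and 12.9% (ERaKO). It put endothelial shares at 34.5% (male), 31.9% (female) and 29.6% (ERaKO) and mesangial shares at 8.88% (male), 2.32% (female) and 8.84% (ERaKO). A cluster resolution of 0.5 put parietal shares at 4.94% (male), 3.76% (female) and 9.75% (ERaKO) and podocytes per 100 podocytes and parietal cells at 87.9 (male) and 92.7 (female). Progenitor was 0.34 and slit diaphragm was −0.24 in ERaKO parietal cells. Classes assigned cell by cell put parietal shares at 4.63% (male) and 10.0% (ERaKO) and podocyte shares at 49.6% (female). It put tubule shares at 8.38% (ERaKO). Npnt was −0.030 (reversed from 0.38), immediate early was 0.097, heat shock was 0.22 and Notch was 0.31 in male parietal cells. Progenitor was 0.30, oestrogen was 0.33, injury was −0.41 and basement membrane was −0.045 (reversed from 0.27) in ERaKO parietal cells. Slit diaphragm was −0.63 in ERaKO parietal cells, immediate early was 0.32 and matrix was 0.038 (reversed from −0.66) in male endothelial cells, and angiogenic was −0.0034 in ERaKO endothelial cells. Matrix was 0.41 and immediate early was 0.30 in male mesangial cells, immediate early was 0.54 in ERaKO mesangial cells, and female-biased was −6.42 in male tubule cells. Abcc3 was 0.016 (reversed from −0.29), Ccl2 was −0.49 (reversed from 1.27), Spp1 was −0.34 (reversed from 0.25) and injury was −0.055 (reversed from 0.71) in ERaKO tubule cells. Oxidative phosphorylation was 0.29 and parietal genes was −0.25 (reversed from 0.95) in ERaKO tubule cells. Keeping doublets put podocyte shares at 29.9% (ERaKO). Angiogenic was −0.015 and matrix was 0.23 (reversed from −0.66) in male endothelial cells, matrix was 0.51 in ERaKO endothelial cells, and basement membrane was 0.11 (reversed from −1.69) in male phagocyte cells.

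Thinning cells to 2000 UMIs put podocyte shares with a colour at 1.48% (male), 1.87% (female) and 0.635% (ERaKO) and podocyte shares with Esr1 at 0% (male) and 0% (female). It put parietal shares with Esr1 at 0% (male) and 0.481% (ERaKO) and smooth muscle and renin shares with Esr1 at 3.99% (male), 5.23% (female) and 2.11% (ERaKO). Next came cycling podocyte shares at 0% (male) and 0% (female) and cycling parietal shares at 0% (male), 0% (female) and 0% (ERaKO). Transcription factor was 0.21, oestrogen was −0.036 (reversed from 0.19), immediate early was 0.53 and injury was 0.44 in male podocyte cells. Heat shock was 0.24, cell cycle was 0.54 and male-biased was 0.13 in male podocyte cells. Oestrogen was −0.10, injury was 0.59, cholesterol was −0.025 (reversed from 0.23) and oxidative phosphorylation was −0.018 in ERaKO podocyte cells. Receptor was 0.10 and cell cycle was 0.36 in ERaKO podocyte cells. Oestrogen was 0.33, injury was −0.19, interferon was −0.74 and immediate early was 0.37 in male parietal cells. Slit diaphragm was 0.072 in male parietal cells. Per3 was 0.87 (reversed from −1.10), progenitor was 0.56, interferon was −0.48 and immediate early was 0.26 in ERaKO parietal cells. Interferon was −0.50, immediate early was 0.39, heat shock was 0.34 and matrix was −0.096 in male endothelial cells. Cholesterol was 0.40, retinoid was 0.85, interferon was −0.51 and angiogenic was −0.16 in ERaKO endothelial cells. Immediate early was −0.023 and heat shock was −0.29 in ERaKO endothelial cells, and Pdgfrb was −0.030 (reversed from 0.27) and immediate early was 0.34 in male mesangial cells. Itga8 was 0.037 (reversed from −0.15) and immediate early was 0.33 in ERaKO mesangial cells. Male-biased was 4.09, injury was −0.43, oxidative phosphorylation was 0.16 and parietal genes was −0.38 (reversed from 0.59) in male tubule cells. Slc22a19 was −0.038 (reversed from 0.27), Abcc3 was 0.023 (reversed from −0.29), male-biased was −0.23 and oxidative phosphorylation was 0.27 in ERaKO tubule cells. Csnk2a2 was −0.26 (reversed from 1.01) in male smooth muscle and renin cells.

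Counting hrGFPIINLS as a colour put podocyte shares with a colour at 18.9% (male), 20.9% (female) and 11.6% (ERaKO). A minimum of 5 cycling UMIs put cycling podocyte shares at 0% (female) and cycling parietal shares at 0.820% (male), 0% (female) and 0% (ERaKO). A minimum of 200 CPM put r at 0.457 (podocyte), 0.492 (parietal), 0.259 (endothelial), 0.494 (mesangial) and 0.197 (tubule). Leaving out haemoglobin genes put r at 0.333 (podocyte) and 0.350 (endothelial). Leaving out sex chromosome and haemoglobin genes put r at 0.463 (podocyte), 0.630 (parietal), 0.462 (endothelial) and 0.738 (mesangial).

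Splitting the female cells put r at 0.249 (parietal), 0.146 (mesangial) and 0.220 (tubule). With each cell scaled equally, slit diaphragm was 0.14, immediate early was 0.53 and oxidative phosphorylation was −0.10 in male podocyte cells. Slit diaphragm was −0.016, basement membrane was 0.30 and immediate early was 0.63 in ERaKO podocyte cells. Interferon was −0.54 and immediate early was 0.38 in male parietal cells. Progenitor was 0.25, oestrogen was 0.32, immediate early was 0.28 and slit diaphragm was −0.37 in ERaKO parietal cells. Interferon was −0.53 and matrix was −0.092 in male endothelial cells, and Itga8 was 0.077 (reversed from −0.15) and immediate early was 0.57 in ERaKO mesangial cells. Male-biased was 3.44, female-biased was −5.21, injury was −0.32 and oxidative phosphorylation was 0.21 in male tubule cells. Oxidative phosphorylation was 0.25 in ERaKO tubule cells.

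In lists without members more abundant in other classes, oestrogen was −0.0021 (reversed from 0.19) and interferon was −0.30 in male podocyte cells. Basement membrane was 0.067, oestrogen was −0.096, interferon was −0.58 and cholesterol was −0.092 (reversed from 0.23) in ERaKO podocyte cells. Heat shock was 0.17 and slit diaphragm was 0.079 in male parietal cells, and injury was −0.33 and slit diaphragm was 0.17 in ERaKO parietal cells. Matrix was −0.11 in male endothelial cells, immediate early was −0.064 and matrix was 0.051 in ERaKO endothelial cells, and male-biased was 3.32 in male tubule cells. Injury was 0.36 in ERaKO tubule cells. With a pseudocount of 5 CPM, interferon was −0.32, male-biased was 0.52 and female-biased was −0.22 in male podocyte cells, and interferon was −0.51 in ERaKO podocyte cells. Matrix was −0.40 in male endothelial cells, and female-biased was −3.70 in male tubule cells. With TMM factors, oxidative phosphorylation was −0.093 in male podocyte cells, immediate early was 0.40 in male parietal cells, immediate early was −0.19 in ERaKO endothelial cells, and oxidative phosphorylation was −0.032 (reversed from 0.12) in male tubule cells. Oxidative phosphorylation was 0.11 in ERaKO tubule cells. With a member minimum of 100 counts, male-biased was 0.13 in male podocyte cells, matrix was −0.12 in male endothelial cells, and male-biased was 3.32 in male tubule cells. With a member minimum of 5 counts, female-biased was −0.32 in male podocyte cells, injury was −0.57 in male parietal cells, retinoid was 0.092 in male endothelial cells, and angiogenic was 0.0048 (reversed from −0.031) in ERaKO endothelial cells. Opposite-phase clock was −0.18 (reversed from 0.53) in male phagocyte cells. At a cluster resolution of 2, injury was 0.14 in ERaKO podocyte cells. With median-of-ratios factors, immediate early was 0.39 in male parietal cells, immediate early was −0.19 in ERaKO endothelial cells, oxidative phosphorylation was −0.028 (reversed from 0.12) in male tubule cells, and oxidative phosphorylation was 0.10 in ERaKO tubule cells.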

Other observations

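All values in this part come from classes, lists and genes chosen after their values were seen.

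Smooth muscle and renin cells, the wall cells of the glomerular arterioles, had more renin RNA in the female ERaKO library than in the female one. Ren1, which encodes renin, was 2.45-fold higher in the female ERaKO cells (log2 ratio 1.29, 1.28 to 1.31, 157436 against 46472 counts), at 93990.4 CPM against 38421.1 in female and 49293.2 in male cells. Cluster 9, led by Ren1 and Akr1b7, held 97 of 237 such cells in the female ERaKO library, 30 of 153 in the female library and 89 of 276 in the male one. The higher Ren1 of the class therefore cannot be told apart from a larger share of cluster 9 cells. Ren1 within cluster 9 was not compared between the libraries. Dclk1 (1.66), Cnn1, a contractile protein of smooth muscle (1.54), Plp2 (1.34) and Plpp5 (1.29) were also higher, and Nr4a2 (−2.22), the clock gene Nr1d1 (−1.89), Ppp1r15a (−1.88), Irs2 (−1.66) and Nfkbiz (−1.65) were lower. In these cells immediate early genes had a median of −1.10 (11 of 14 members 1.5-fold lower) and cholesterol synthesis genes one of 1.01 (7 of 12 higher), against −0.08 and 0.32 in the male cells. Male cells had more Vgll3 (1.10), Prss23 (1.05), Adgrl3 (1.04), Ddah1 (1.02) and Csnk2a2 (1.01) and less G0s2 (−1.43), Nr1d1 (−1.07) and Gadd45b (−1.06).

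Mononuclear phagocytes numbered 91, 71 and 52 cells in the male, female and female ERaKO libraries. All came from cluster 10, whose cell subtypes were not separated. A different mixture of subtypes thus cannot be told apart from changed levels within cells. Female ERaKO phagocytes had more Irf8, a factor of monocyte and dendritic cell fate (1.68, 1.31 to 2.06), Lgals1 (1.34), Tecr (1.24), Itgb7 (1.03) and Mrps16 (0.95), and less Spn (−1.42), Rassf3 (−1.30), Ptpra (−1.29), Ace (−1.28) and the uncertain AY036118 (−1.35). Male phagocytes had more Tppp3 (1.62), Cfp, the complement factor properdin (1.28), Hist1h1c, Hist1h1e and Mrpl23 (1.37 to 1.27), and less Ccl4, a chemokine (−1.76, −1.98 to −1.55), Zfp36l1 (−1.28), Tgfbr2 (−1.26) and Slfn5 (−1.14). Lists of other cell types were lower in the same male cells, with medians of −1.05 for slit diaphragm genes (11 of 16 lower), −1.69 for basement membrane genes (4 of 4) and −2.90 for angiogenic genes (6 of 6). With doublets kept these medians were −0.30, 0.11 and −1.39.

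A list of 12 glucocorticoid-responsive genes had medians below 0 in the female ERaKO library in the 7 classes examined, but not with every member lower. The medians were −0.22 in podocytes (12 genes, percentile 0.53, 5 lower, 2 higher), −0.80 in parietal (12 genes, percentile 0.0, 7 lower), −0.38 in endothelial (11 genes, percentile 0.0, 5 lower) and −0.35 in mesangial cells (11 genes, percentile 0.07, 1 lower). They were −0.65 in proximal tubule cells (12 genes, percentile 0.0, 7 lower), −0.69 in smooth muscle and renin cells (10 genes, percentile 0.01, 5 lower) and −0.39 in phagocytes (9 genes, percentile 5.50, 2 lower). In the male library the medians were −0.19, −0.16, 0.16, 0.01, −0.09, −0.35 and −0.24 in the same order.

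The loss of Lpl was not shared by every class of the female ERaKO library. Levels in the male, female and female ERaKO libraries were 968.8, 1042.2 and 45.1 CPM in podocytes, 471.6, 544.8 and 32.3 CPM in endothelial cells and 32.5, 32.9 and 9.47 CPM in parietal cells. They were 355.2, 382.1 and 592.5 CPM in mesangial cells, 297.9, 296.8 and 290.7 CPM in smooth muscle and renin cells and 213.0, 552.4 and 415.5 CPM in proximal tubule cells. In phagocytes, outside the Pax2 lineage, they were 75.6, 261.3 and 18.4 CPM (50, 175 and 7 counts), in unnamed cells 473.6, 604.4 and 55.3 CPM and in T or NK cells 44.8, 202.0 and 94.6 CPM. How much of the Lpl RNA in phagocytes and T or NK cells came from other classes was not measured. Rab6b, a Golgi transport protein outside the naming rule because other classes hold more of it, stood at 11.5, 9.01 and 108.0 CPM in podocytes. It was found in 7.41%, 6.49% and 53.5% of them. The rise was not particular to podocytes, with 9.05, 6.92 and 48.3 CPM in parietal cells. Levels were 4.69, 12.95 and 40.15 CPM in endothelial and 1.63, 1.18 and 13.9 CPM in proximal tubule cells. In classes with more of it, they were 211.1, 196.6 and 279 CPM (mesangial) and 300.2, 262.1 and 296.7 CPM (smooth muscle and renin). How much of the Rab6b RNA came from other classes was not measured. Haemoglobin RNA was uneven, with Hbb-bs at 415.5, 5.43 and 423.8 CPM in podocytes and 533.8, 672.6 and 16.8 CPM in endothelial cells, where 1 cell held 98.2% of the male and 96.2% of the female counts. The unnamed cluster 5, with podocyte markers beside Cst12 and Pla2g7, held 149 male, 156 female and 75 female ERaKO cells.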
